A study of Mus musculus with 18 samples.

How the data were processed

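Liver RNA of C57BL/6 mice was measured on 18 Affymetrix whole-transcript arrays, 1 array per sample. Per the series description, Pten was deleted in the liver (loxP-flanked Pten with Cre under the albumin promoter). Per the labels, the mice were wild type or mutant, and the tissue was taken after an overnight fast. Total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment and labelled with biotin. The groups were wild type at 3 months (5 arrays), mutant at 3 months (5 arrays), wild type at 15 months (5 arrays) and mutant at 15 months (3 arrays), taken from the labels. The labels number the replicates but do not say that each came from a separate animal, so p-values measure the spread between these samples.

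The deposited table gives 28858 probe sets per array as log values made with Affymetrix Expression Console, per the submitters' processing notes. The summary method, the normalization and the version are not given in the sources used here. The base of the deposited log values is not stated, and natural log was inferred from their range. The highest deposited value, 10.71, is a signal of 44802 units as a natural log, near the range of a 16-bit scanner, and of 1675 units as log2. The deposited natural log values were divided by ln 2 (0.693) to give log2 signal. If the deposited scale were log2, every log2 change given here would have to be multiplied by 0.693, and p-values from the limma fits on these values would not change. The array medians lay between 4.40 and 4.64 on the deposited scale. Between 77 and 368 values per array were exactly 0, and values at this floor have no order. Detection calls were not used here, and the number of arrays limits the precision.

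Probe sets were named with the platform's gene table. Of the 28858 probe sets, 21776 had 1 gene symbol, 1618 had several and were not named, and 5464 were not listed. The Entrez identifiers of 21686 of the 21776 matched the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed through that match. Where a gene had several probe sets (993 genes), the one with the highest mean over all arrays was used, which left 19933 genes. Older symbols of the table (such as G6pc and Arntl) are kept. Members of close gene families, such as the Mup, Cyp2c, Sult and Gstm genes, can share probe sequence, so their changes are uncertain between family members. Probes of the targeted gene, Pten, were not analysed here because no probe set had that single name, so the check of the deletion on each array was not run. Gck, Spp1 and Ddx3y, also chosen for naming, were not analysed here for the same reason.

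A linear model of the 4 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend). Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the 19933 genes, with no fold threshold. All adjusted p-values of single genes are from this limma model. The contrasts were mutant against wild type at each age, the difference of these effects between the ages (interaction), and 15 against 3 months in each genotype. Of 36 gene lists fixed before the data were examined, 34 had at least 5 measured genes and were tested with camera, a competitive test against all other genes, at its preset correlation of 0.01, with adjustment over the lists. The same test with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction, were alternatives. For each list called in a genotype comparison or in the interaction, median, mean and test had the same sign. They differed in sign for some lists that were not called.

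The rule for naming genes was fixed before the data were examined. For each genotype comparison it took, among genes past the threshold whose groups did not overlap, the 10 largest increases and the 10 largest decreases, leaving out provisional names. It took the 5 largest in each direction for the interaction and for each age comparison (without overlap between groups in the age comparisons), up to 4 members of each list with the smallest p in each genotype comparison, and Afp, Gpc3, Fasn, Cd36, Pparg, Mki67, Alb and Xist in any case. The text gives part of the list members so named.

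On simulated data with the means and spreads of these 19933 genes, a 2-unit log2 change was recovered for 91% of 100 changed genes in the comparison at 3 months and for 87% in that at 15 months. A 1-unit change was recovered for 46% and 17%. Of the 19733 unchanged genes, 0.020% and 0.041% were called. The simulated noise was independent between genes and held no outlying arrays, so these shares do not give the rate of false calls in the real data. Alternatives planned before the data were examined were quantile normalization, centring of each array on its median, leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, eBayes with trend and robust, array weights, a fit to the groups compared alone, a replicate block and leaving out each array. A log2(signal + 16) scale and fits without doubted arrays were added after the data were examined. The Y-linked mean was at least 6.26 and Xist at most 4.33 on all arrays. Xist, the X-inactivation transcript, thus lay below the lowest array median of 6.35 on every array. The lowest Y-linked mean, on wild type replicate 4 of 3 months, also lay below 6.35, and Xist was 0.07 on that array. The low Xist values argue against female samples. Levels of different probes are not on the same scale, so these values do not decide the sex. The Y-linked mean as a covariate, planned for samples of both sexes, was run after the results were seen. It ranged from 8.03 to 8.42 in wild type and from 7.27 to 7.99 in mutant livers at 15 months, so it shares variation with the groups. The other pseudocount applied to linear values and was not run.

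The serial numbers in the sample names fell in separate ranges for the ages, with both genotypes in each range. Within each range all wild type numbers came before the mutant numbers. The labels name no batch. If the ages were processed apart, age and processing batch cannot be told apart. Each genotype comparison lies within 1 age, but an effect of processing order within an age could not be told apart from genotype. The median change over all genes from 3 to 15 months was 0.26 (wild type) and 0.20 (mutant) log2 units. The highest correlation between any pair of arrays was 0.964, so no array looked like a copy of another.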

Results

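The series compared livers of mice with a liver-specific deletion of Pten, the lipid phosphatase that opposes PI3-kinase signalling, with wild type livers. Tissue was taken at 3 months, which the submitters call the steatosis stage, and at 15 months, the tumour stage. Transcript levels of 19933 genes were measured on 18 arrays: 5 wild type and 5 mutant arrays at 3 months, and 5 wild type and 3 mutant arrays at 15 months. Levels are log2 signal, with the natural log base of the deposited values inferred, and changes are log2 differences of group means with their standard error (SE). Array medians ranged from 6.35 to 6.47 log2 units in wild type and from 6.36 to 6.43 in mutant livers at 3 months, and from 6.52 to 6.69 and from 6.58 to 6.69 at 15 months. Albumin (Alb) did not pass the test in either genotype comparison, with changes of 0.05 (SE 0.12, adjusted p = 0.844) at 3 months and 0.07 (SE 0.14, adjusted p = 0.826) at 15 months. With each array left out in turn Alb changed by -0.0173 to 0.0909 and by 0.0173 to 0.1039.

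The comparison at 3 months asked how the liver transcriptome differed at the steatosis stage. The largest increase in mutant livers was that of Cidea (probe set 10456392), which encodes a lipid droplet protein. Its level was 1.60 ± 1.46 (SD, n = 5) in wild type and 11.08 ± 0.41 (SD, n = 5) in mutant livers, a difference of 9.48 (SE 0.90, adjusted p = 0.000109). Because wild type levels lay near the floor, the change on the log2(signal + 16) scale, 6.76, is the safer size. The monoacylglycerol acyltransferase Mogat1 rose by 4.38 (SE 0.73) and the neurotrophin receptor gene Ntrk2 by 4.10 (SE 0.59). They were followed by the thyroxine-binding globulin gene Serpina7 (4.00, SE 0.51), the galectin gene Lgals1 (3.82, SE 0.47) and Serpina12, which encodes vaspin (3.52, SE 0.46). The chemokine gene Ccl3 rose by 3.32, Thrsp, a regulator of lipogenesis, by 3.25, Cyp2a22 by 3.20 and Themis by 3.20. Each mutant array lay above each wild type array for all 10 of these genes. Among genes past the test whose groups did not overlap, the largest decreases were those of Susd4 (-3.31, SE 0.54), Enho, which encodes adropin (-3.20, SE 0.43), Zg16 (-3.07, SE 0.83) and Myoz1 (-2.26, SE 0.63). They were followed by the leptin receptor gene Lepr (-1.65), Acmsd (-1.65), the insulin receptor substrate gene Irs2 (-1.65), Nipal1 (-1.46), the aspartate aminotransferase Got1 (-1.44) and Hhatl (-1.44).

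In the list of lipid uptake, storage and droplet genes, 8 of 29 measured members rose and 2 fell (10 and 2 adjusted over the list alone). The fatty acid transporter Cd36 rose from 9.67 ± 0.39 to 11.70 ± 0.33 (SD, n = 5 each), which is 4.07-fold, Fitm1 rose by 1.98 (SE 0.30) and Abhd5, a coactivator of triglyceride lipase, by 0.89 (SE 0.14). The list as a whole was shifted upward (median 0.49, camera adjusted p = 0.00244), though not with an estimated correlation (adjusted p = 0.647). Of 24 genes of de novo lipogenesis, 5 rose and none fell (9 adjusted over the list alone), among them the desaturases Scd1 (3.73-fold, change 1.90, SE 0.37) and Scd2 (4.95-fold, change 2.31, SE 0.49) and the malic enzyme Me1 (1.13, SE 0.27). Their shift (median 0.61, camera adjusted p = 0.00219) had an adjusted p = 0.738 with an estimated correlation. Fasn, the fatty acid synthase, changed by 0.67 (SE 0.82, adjusted p = 0.677) and did not pass; its change was 0.10 (adjusted p = 0.955) without mutant replicate 4 and 1.003 without mutant replicate 5. Pparg, a lipogenic nuclear receptor, rose by 1.34 (SE 0.23, adjusted p = 0.00627).

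The list of NRF2 target and glutathione genes was also shifted upward at 3 months (median 0.38, camera adjusted p = 2.0e-06, 5 of 30 members higher, 7 adjusted over the list alone), with an adjusted p = 0.260 with an estimated correlation. The glutathione transferases Gstm3 (8.27-fold, change 3.05, SE 0.43), Gstm2 (1.13, SE 0.26) and Gsta3 (0.91, SE 0.23) and the glutathione synthesis gene Gclc (0.95, SE 0.22) rose. Interferon-stimulated genes (2 of 26 members higher, 3 adjusted over the list alone, among them Oas2), oxidative phosphorylation genes (1 of 39 higher, Cox6c, 2 adjusted over the list alone) and female-biased liver genes (3 of 19 higher, 4 adjusted over the list alone, among them Ntrk2, Cyp2a22 and Abcd2) were shifted upward. Their medians were 0.43, 0.18 and 0.40, and their camera adjusted p-values were 0.00373, 0.00380 and 0.0288. With an estimated correlation these lists had an adjusted p = 0.647, an adjusted p = 0.873 and an adjusted p = 0.647. Periportal genes were shifted downward (median -0.37, camera adjusted p = 0.0229, adjusted p = 0.647 with an estimated correlation) although none of the 14 members passed the test over all genes (1 lower adjusted over the list alone). The list of FoxO target and gluconeogenic genes did not pass as a group (camera adjusted p = 0.0743), but some members passed. Irs2, Got1 and Igfbp1 (-1.41, SE 0.36) fell and Sesn3 rose by 0.81 (SE 0.21). Among PI3K-AKT pathway genes, Pik3r1 rose by 1.20 (SE 0.25) and Rheb by 0.82 (SE 0.21). None of the cell cycle list but Kif11, a mitotic kinesin near the floor in wild type, passed the test.

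Markers of the exocrine pancreas were lower in mutant livers at 3 months (median of 15 genes -3.07, camera adjusted p = 2.0e-06, adjusted p = 0.647 with an estimated correlation), with 1 member past the test over all genes, Zg16, and 12 adjusted over the list alone. The mean over these 15 genes was 7.68 in wild type replicate 1 and 11.04 in wild type replicate 5. It lay between 2.52 and 3.36 in the other wild type livers and between 2.63 and 2.82 in mutant livers. The mean over 20 skeletal muscle genes, chosen after the data were examined, was 8.92 in wild type replicate 3, in which Myoz1 was also highest, and 6.25 in wild type replicate 1, and lay between 3.88 and 4.46 on the other arrays of this age. Zg16 and Myoz1 lost their calls on the log2(signal + 16) scale (adjusted p = 0.104 and 0.102).

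**Figure D1:**
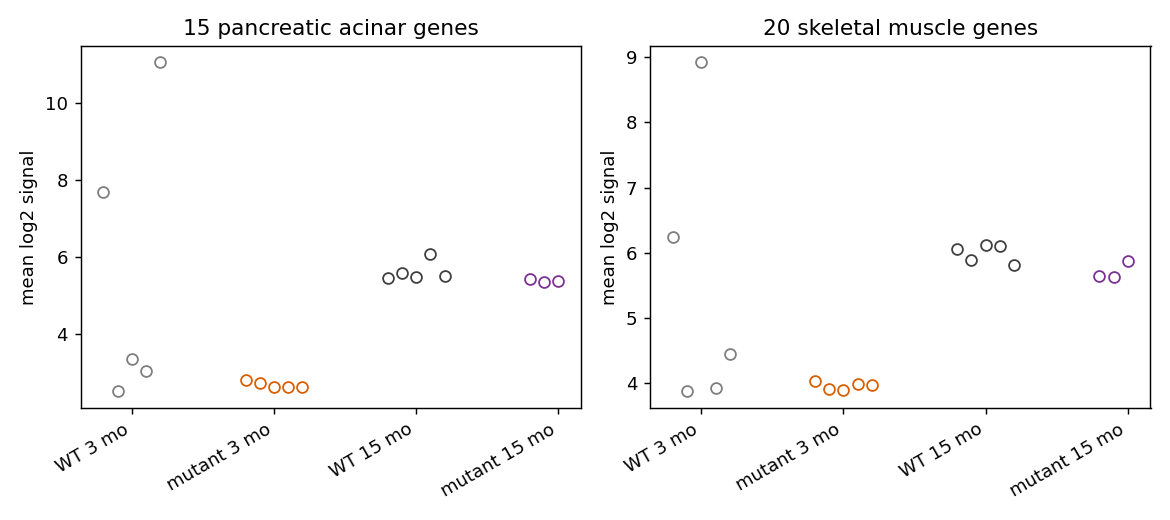
Mean log2 signal (vertical axes) of 15 pancreatic acinar genes (left) and 20 skeletal muscle genes (right) on each array, 1 circle per array, by group. Acinar signal reached 11.04 on 1 wild type array of 3 months and muscle signal reached 8.92 on another, while the mutant arrays of 3 months lay between 2.63 and 2.82 for acinar genes. All arrays of 15 months lay between 5.35 and 6.07 for acinar genes and between 5.63 and 6.12 for muscle genes.

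In all, 876 of 19933 genes differed at 3 months, 755 higher and 121 lower in mutant livers (limma adjusted p below 0.05). Over all genes tested, the groups did not overlap for 1480 (7.42%), while chance would separate 0.794%. With quantile normalization 561 were higher and 168 lower. The count depended on single arrays: it was 447, 522 and 333 without wild type replicates 1, 3 and 4, and 268, 253, 286 and 384 without mutant replicates 1, 2, 3 and 5. Without the wild type arrays of high acinar signal (replicates 1 and 5) it was 349 (323 higher and 26 lower). Without those of high acinar or muscle signal (replicates 1, 3 and 5) it was 120 (114 higher and 6 lower), and 93 of the 876 calls were kept. Without the pair with most values at 0 (replicates 1 and 4) it was 147 (132 higher and 15 lower). Most calls of lower genes thus ended in these fits. With only the arrays of 3 months in the fit the count was 357. Other settings raised it, to 1430 and 1500 without the dimmest 25% and 50% of genes, to 1429 with trend and robust eBayes and to 1385 with array weights. With the Y-linked mean as a covariate, run after the results were seen, it was 189. Under that covariate the calls of Thrsp, Cyp2a22, Zg16, Myoz1, Pik3r1, Rheb, Igfbp1, Sesn3, Me1, Abcd2, Kif11, Gstm2, Gclc, Gsta3, Hamp, Oas2 and Cox6c ended. Of the 20 genes named for size, 14 kept their call whichever array was left out. The calls of Thrsp, Zg16, Myoz1, Lepr, Acmsd and Nipal1 ended in 12, 13, 15, 6, 3 and 4 of the 18 fits, and Myoz1 changed by -1.40 without wild type replicate 3. Among the list members, the calls of Rheb, Igfbp1, Sesn3, Scd2, Me1 and Kif11 ended in 7, 7, 9, 1, 5 and 13 fits. Those of Gstm2, Gclc, Gsta3, Hamp, Oas2 and Cox6c ended in 5, 5, 7, 7, 6 and 15.

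Single arrays also moved lists at 3 months. The oxidative phosphorylation median was 0.11 without wild type replicate 1 (adjusted p = 0.0975), and the call of the female-biased list ended without wild type replicate 2 (adjusted p = 0.0699). The periportal call ended without wild type replicate 2 (adjusted p = 0.113) or mutant replicate 1 (adjusted p = 0.0581). The median was 0.35 for lipogenesis without mutant replicate 4, 0.60 for female-biased genes without wild type replicate 5 and -1.68 for acinar markers without wild type replicate 5. The calls of the female-biased and oxidative phosphorylation lists ended with the Y-linked mean as a covariate.

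The comparison at 15 months asked how the livers differed at the tumour stage. Among named genes past the test whose groups did not overlap, the largest increase was that of Guca2b. This gene, which encodes uroguanylin, was 3.65 ± 3.14 (SD, n = 5) in wild type and 10.47 ± 0.76 (SD, n = 3) in mutant livers, a change of 6.82 (SE 1.12, adjusted p = 0.000727). The chemokine gene Ccl20 rose by 6.41 (SE 1.00), the antimicrobial lectin gene Reg3g by 6.11 (SE 0.86) and the actin-bundling gene Pls1 by 5.53 (SE 1.19). The epithelial transcription factor gene Ehf rose by 5.37 (SE 0.77), the integrin gene Itgb6 by 5.36 (SE 0.98) and Tspan8 by 5.34 (SE 0.93). Gp2, Elovl7 and Timp4 rose by 5.17, 5.14 and 5.11. Wild type levels of these 10 genes were low, and on the log2(signal + 16) scale their changes were smaller, for example 5.11 for Guca2b, 4.47 for Ccl20 and 2.42 for Itgb6. By the same rule, the largest decreases were those of the fatty acid elongase Elovl3 (-5.10, SE 1.02), the sulfotransferases Sult2a8 (-4.93, SE 0.79) and Sult5a1 (-3.80, SE 0.60), Igfbp2 (-4.03, SE 0.76), and the bile acid 12-alpha-hydroxylase Cyp8b1 (-4.02, SE 0.76). The major urinary protein genes Mup3 (-4.01, SE 0.61) and Mup21 (-3.38, SE 0.63) fell as well. Neb (-3.98), Vmn2r76 (-3.53) and Susd4 (-3.46) completed the 10. The mutant arrays differed widely for some of them, with 7.09 ± 2.92 for Sult2a8 and 7.72 ± 2.91 for Igfbp2 (SD, n = 3).

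Cholangiocyte and progenitor markers were shifted most among the lists at 15 months (median 3.83, camera adjusted p = 1.08e-25). Of 22 measured members 20 rose and none fell (21 adjusted over the list alone), and the shift passed with an estimated correlation (adjusted p = 0.0187). Prom1 rose by 4.42 (SE 0.38), the tight junction gene Cldn7 by 4.17 (SE 0.42), Cd24a by 4.90 (SE 0.56) and Ezr by 2.51 (SE 0.27). Oncofetal and liver tumour markers (18 of 25 higher, 21 adjusted over the list alone, median 2.71, camera adjusted p = 9.96e-13) and stellate cell and extracellular matrix genes (26 of 36 higher, 29 adjusted over the list alone, median 1.60, camera adjusted p = 4.31e-18) passed with an estimated correlation as well (adjusted p = 0.0303 and adjusted p = 0.0453). Among them were Golm1 (3.12, SE 0.43), Anxa2 (2.88, SE 0.40) and S100a11 (3.00, SE 0.42). So were Col1a2, a chain of type I collagen, which rose 6.04-fold (2.59, SE 0.35), Timp1 (2.94, SE 0.41) and Timp2 (1.94, SE 0.23). The alpha-fetoprotein gene Afp rose by 1.40 (SE 0.41, adjusted p = 0.0323), but its call ended in 4 of 18 fits without 1 array. Without mutant replicate 1 Afp changed by 0.59 (adjusted p = 0.197). Gpc3 changed by 2.93 (SE 0.97, adjusted p = 0.0600) and did not pass. Gpc3 changed by 1.58 (adjusted p = 0.372) without mutant replicate 2, and it passed without mutant replicate 1 (4.07, adjusted p = 0.0201) and without wild type replicate 3 (3.54, adjusted p = 0.0182).

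**Figure D2:**
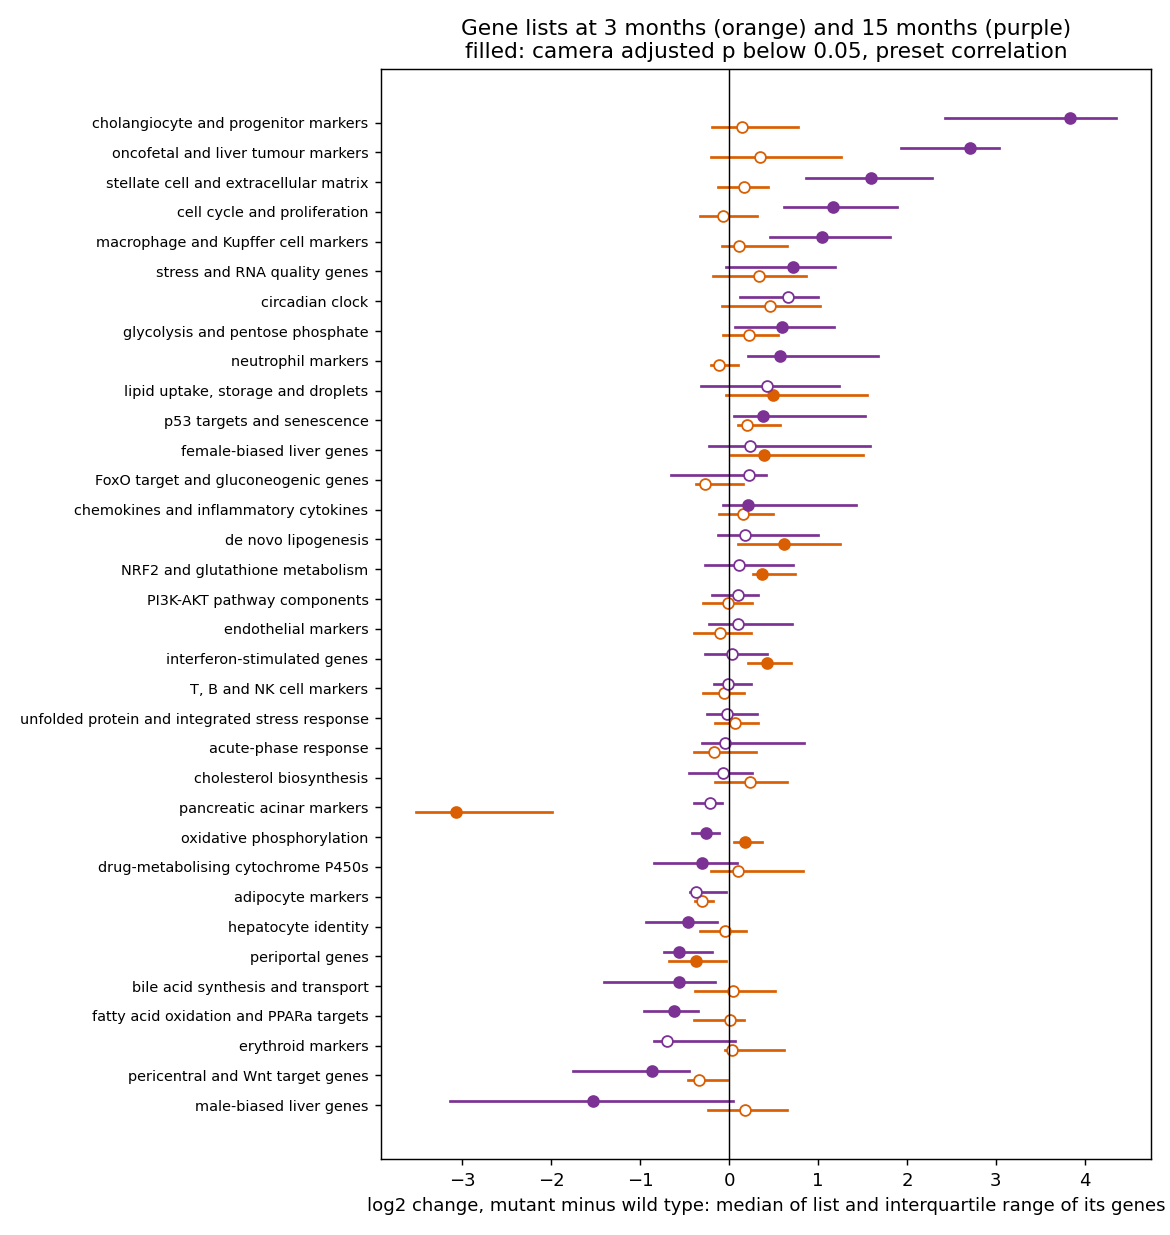
Median log2 change (mutant minus wild type, horizontal axis) of each of 34 gene lists at 3 months (orange) and 15 months (purple), with lines for the interquartile range of the genes of a list. Cholangiocyte and progenitor markers had the highest median at 15 months (3.83), and pancreatic acinar markers the lowest at 3 months (-3.07).

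Proliferation genes were higher in mutant than in wild type livers at 15 months. Of 38 members of the cell cycle list 18 were higher and none lower (25 adjusted over the list alone, median 1.17, camera adjusted p = 2.66e-11), with an adjusted p = 0.0669 with an estimated correlation. From 3 to 15 months the median of this list changed by -0.72 in wild type and by 0.01 in mutant livers. The difference at 15 months thus went with a lower wild type level, in a comparison where processing cannot be told apart from age. The mitotic cyclin gene Ccna2 rose by 2.23 (SE 0.41), Mki67, which encodes the proliferation antigen Ki-67, by 2.29 (SE 0.47), and Top2a by 2.41 (SE 0.43), though with the mean of its probe sets Top2a changed by 0.68 (adjusted p = 0.264). Macrophage markers (11 of 28 higher and 1 lower, 20 and 1 adjusted over the list alone), neutrophil markers (5 of 15 higher, 6 adjusted over the list alone) and chemokines and cytokines (9 of 33 higher and 1 lower, 11 and 1 adjusted over the list alone) were shifted upward (camera adjusted p = 5.78e-06, 0.00119 and 0.00119). Itgam rose by 3.10 (SE 0.37), S100a8 by 2.39 (SE 0.41), Ccl2 by 3.02 (SE 0.40) and Tgfb2 by 4.56 (SE 0.68). With an estimated correlation these lists had an adjusted p = 0.330, an adjusted p = 0.198 and an adjusted p = 0.0518. The list of T, B and NK cell markers had no member past the test (median -0.01, camera adjusted p = 0.991). Glycolysis and pentose phosphate genes (6 of 21 higher, 7 adjusted over the list alone, camera adjusted p = 0.000383), p53 target and senescence genes (7 of 17 higher, 7 adjusted over the list alone, camera adjusted p = 0.0160) and stress and RNA quality genes (5 of 15 higher, 5 adjusted over the list alone, camera adjusted p = 0.0140) were shifted upward too, with an adjusted p = 0.0892, an adjusted p = 0.153 and an adjusted p = 0.315 with an estimated correlation. The hexokinase Hk2 rose by 3.25 (SE 0.39), Pkm by 1.51 (SE 0.20), Phlda3 by 2.91 (SE 0.62) and Jun, an immediate-early gene that also responds to tissue handling, by 1.87 (SE 0.40).

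Lists of hepatocyte function were shifted downward at 15 months. Of 25 genes of bile acid synthesis and transport 10 fell and 1 rose (14 and 3 adjusted over the list alone, median -0.57, camera adjusted p = 2.86e-05), among them Cyp8b1, the uptake transporter Slco1b2 (-1.58, SE 0.32), Hsd3b7 (-1.40, SE 0.29) and Cyp7b1 (-2.03, SE 0.46). In the hepatocyte identity list 7 of 26 fell (10 adjusted over the list alone, camera adjusted p = 3.09e-06), such as Hgd (-1.03, SE 0.17) and Uox (-1.35, SE 0.27). In fatty acid oxidation 5 of 29 fell (8 adjusted over the list alone, camera adjusted p = 1.95e-06), such as Fabp1 (-2.02, SE 0.30) and Cpt2 (-0.85, SE 0.23). In male-biased genes 6 of 16 fell (8 adjusted over the list alone, camera adjusted p = 2.86e-05), and in pericentral genes 6 of 19 fell (11 adjusted over the list alone, camera adjusted p = 1.13e-05), such as Oat (-2.35, SE 0.42). With an estimated correlation these 5 lists, in this order, had an adjusted p = 0.0669, an adjusted p = 0.198, an adjusted p = 0.345, an adjusted p = 0.198 and an adjusted p = 0.198. Drug-metabolising cytochrome P450s (4 of 24 lower, 7 adjusted over the list alone, camera adjusted p = 0.00498), oxidative phosphorylation genes (1 of 39 lower, 0 adjusted over the list alone, camera adjusted p = 5.12e-05) and periportal genes (3 of 14 lower and 1 higher, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0140) were shifted downward, with an adjusted p = 0.345, an adjusted p = 0.517 and an adjusted p = 0.263 with an estimated correlation. The higher periportal member was Cdh1, the epithelial cadherin gene (3.45, SE 0.67). Among gluconeogenic genes, whose list did not pass (camera adjusted p = 0.491), G6pc fell by 2.05 (SE 0.41), Fbp1 by 1.02 (SE 0.16) and Pck1 by 1.23 (SE 0.37). The call of Pck1 ended in 6 of 18 fits without 1 array, and its change was -0.73 (adjusted p = 0.279) without mutant replicate 1 and -1.95 without mutant replicate 3. Without mutant replicate 1 the changes of Cyp8b1 (-2.59), Neb (-2.35), Slco1b2 (-0.998) and Cyp7b1 (-1.34, adjusted p = 0.0703) were smaller as well. The calls of Gp2, Cpt2 and Cd36 ended in 6, 2 and 2 of the 18 fits, and that of the p53 target list without mutant replicate 2 (adjusted p = 0.0575). The lipid droplet gene Cidea rose by 4.92 (SE 1.04) and Cd36 by 1.14 (SE 0.30), whereas Pparg changed by 0.25 (SE 0.27, adjusted p = 0.649) and Fasn by 1.96 (SE 0.94, adjusted p = 0.213). With each array left out in turn Pparg changed by 0.1472 to 0.4328, and Fasn changed by 1.26 (adjusted p = 0.608) without mutant replicate 1.

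Single arrays also moved the medians of lists at 15 months. Without mutant replicate 1 the median was -0.26 for hepatocyte identity (-0.46 with all arrays), -0.94 for male-biased (-1.53), -0.43 for pericentral (-0.86) and -0.27 for periportal genes (-0.56), and 0.42 for chemokines (0.21). Without mutant replicate 2 it was -0.30 for hepatocyte identity, 0.39 for chemokines and 0.48 for stress genes (0.72). The P450 median was -0.79 without mutant replicate 3 and -0.49 without wild type replicate 1 (-0.31 with all arrays), and the p53 target median was 0.64 without mutant replicate 3 (0.39). The calls of the periportal list and of Gp2, Neb, Afp, Pck1, Cpt2, Cd36 and Phlda3 ended with the Y-linked mean as a covariate.

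**Figure D3:**
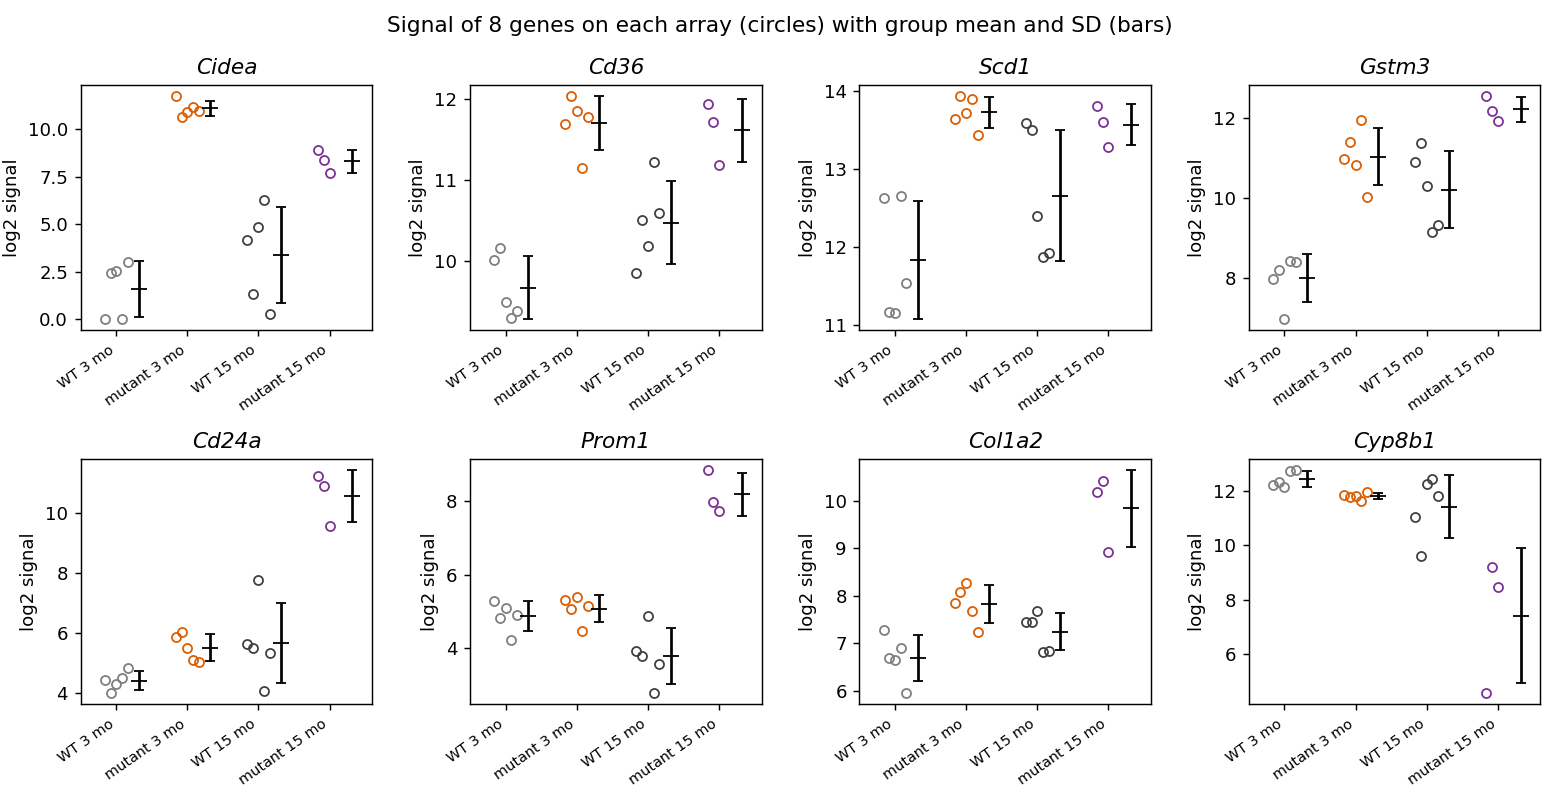
Log2 signal (vertical axes) of 8 genes on each array, 1 circle per array, by group, with bars for the group mean and SD. Cidea was 11.08 ± 0.41 in mutant livers of 3 months against 1.60 ± 1.46 in wild type, and Prom1 was 8.20 ± 0.59 in mutant livers of 15 months against 3.78 ± 0.76 in wild type.

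In all, 2255 genes differed at 15 months, 1642 higher and 613 lower in mutant livers (limma adjusted p below 0.05). Over all genes tested, the groups did not overlap for 3787 of 19933, while chance would separate 3.57%. The fit to the arrays of 15 months alone called 1471, and leaving out mutant replicate 1 or 2 gave 1293 or 1269. The count was 1127 with the Y-linked mean as a covariate. Higher genes made up 72.8% of the calls, and 65.0% with quantile normalization.

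At both ages 175 genes were called, 122 in the same direction (111 higher and 11 lower in mutant livers) and 53 in opposite directions. Independent lists of these sizes would share 62.2 higher and 3.72 lower genes and hold 33.2 genes in opposite directions, so both kinds exceeded that value. The comparisons have no array in common, but both tests use a residual variance per gene that was fitted over all arrays. A gene of low variance can therefore be called more easily at both ages, in either direction, so the lists are not independent. The expected values thus cannot decide whether the excess of shared genes is more than chance. Across genes, which are not independent replicates, the mutant effects at the 2 ages had a Pearson correlation of 0.077. Cidea, Cd36, Ntrk2, Anxa2 and S100a11 were among the genes higher at both ages, and Susd4 and Hamp, which encodes the iron hormone hepcidin (-1.08, SE 0.28 and -1.94, SE 0.32), among those lower at both. The shared count was 53, with the fewest genes, without mutant replicate 2 of 3 months and 43 without the wild type arrays of high acinar or muscle signal. It was 39 with the Y-linked mean as a covariate, 53 with only the groups compared in the fit and 63 without the wild type pair with most values at 0. It was 186 without the dimmest 25% of genes, 195 with trend and robust eBayes and 192 on the log2(signal + 16) scale.

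The test of the difference between the ages asked whether the mutant effect changed from the steatosis to the tumour stage. It called 1934 genes (limma adjusted p below 0.05), with a more positive mutant effect at 15 months for 1071 and a more negative one for 863. This balance turned in other settings, with 948 more positive and 1051 more negative after each array was centred on its median, 799 and 1156 without the dimmest 50% of genes, and 936 and 951 without wild type replicate 5 of 3 months. The test called 63 genes with the Y-linked mean as a covariate, which was run after the results were seen, and none of the 10 genes named next kept its call. The gene calls of this test therefore depend on leaving that covariate out. It shares variation with the groups, so their loss does not decide whether they were false. The largest differences were those of Gp2 (7.23, SE 1.96), Guca2b (7.07, SE 1.48), Ccl20 (6.41, SE 1.33), Reg3g (6.16, SE 1.13) and the intestinal cadherin gene Cdh17 (5.53, SE 1.05) on one side. On the other they were those of Elovl3 (-5.82, SE 1.36), Sult2a8 (-5.63, SE 1.05), Zmat1 (-4.65, SE 1.40), Cidea (-4.56, SE 1.38) and Vmn2r76 (-4.47, SE 0.82). The calls of Zmat1 and Cidea each ended in 13 of 18 fits without 1 array (highest adjusted p = 0.149 and 0.0921), and that of Gp2 in 3. With each array left out in turn, Gp2 changed by 4.75 to 5.85 at 15 months. Part of its difference therefore came from the comparison at 3 months. Wild type replicates 1 and 5 of that age had high acinar signal, and whether this raised their Gp2 level was not tested. For several of these genes the wild type level itself differed between the ages: Guca2b was 8.08 ± 0.08 in wild type and 7.83 ± 0.15 in mutant livers at 3 months (SD, n = 5 each), above the 3.65 ± 3.14 of wild type livers at 15 months. Among the lists, cholangiocyte (median 3.46), oncofetal (2.11), stellate (1.46) and cell cycle genes (1.07) were shifted upward, with camera adjusted p-values of 6.56e-18, 5.59e-07, 5.26e-11 and 1.78e-07. Oxidative phosphorylation (-0.49), fatty acid oxidation (-0.55) and bile acid genes (-0.71) were shifted downward, with camera adjusted p-values of 4.99e-07, 0.00187 and 0.00262. The cell cycle list was shifted downward with age in wild type livers (median -0.72, 18 of 38 lower and 4 higher), though not with an estimated correlation (adjusted p = 0.970). It was not shifted in mutant livers (median 0.01, camera adjusted p = 0.502). The call of fatty acid oxidation ended with the Y-linked mean as a covariate. Of the 15 lists called, 0 passed with an estimated correlation, the lowest being that of the cholangiocyte list (adjusted p = 0.0790). The cell cycle median was 0.64 without mutant replicate 2 of 15 months. Without mutant replicate 1 of 15 months the gene count was 1139, and without the wild type arrays of high acinar or muscle signal at 3 months it was 835. Without the wild type pair with most values at 0 it was 1203.

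Between 15 and 3 months 7582 genes differed in wild type livers (5418 higher and 2164 lower at 15 months) and 4791 in mutant livers (3431 higher and 1360 lower; limma adjusted p below 0.05). The labels name no batch, but the serial numbers of the samples fell in separate ranges for the ages, so a difference in processing cannot be told apart from age here. Acinar means lay between 5.35 and 6.07 on all arrays of 15 months, against 2.63 to 2.82 on mutant arrays of 3 months. Wild type arrays of 3 months ranged from 2.52 to 11.04. After centring each array on its median, 3444 were higher and 3106 lower in wild type and 1955 higher and 2380 lower in mutant livers. The median change over all genes was then 0.06 in wild type and -0.04 in mutant livers, against 0.26 and 0.20 log2 units before. The wild type count was 2528 with the Y-linked mean as a covariate, which ended the call of Slc2a13, 5013 without the dimmest 50% of genes and 4811 without the wild type arrays of high acinar or muscle signal. Among genes past the test whose groups did not overlap, the largest increases in wild type were those of Cep97 (6.10, SE 0.42), Nkg7 (6.04, SE 0.42), Zfp760 (4.93), Csgalnact2 (4.64) and Slc2a13 (4.59). By the same rule, the largest decreases were those of the neuronal sodium channel gene Scn8a (-8.27, SE 0.58), Ccnb2 (-7.53, SE 0.64), Fhdc1 (-7.07), Apbb1 (-6.98) and Trpv4 (-6.85). In mutant livers Moxd1 (6.65, SE 1.62), D17H6S56E-5 (6.54), Gp2 (5.86), Ctrl (5.81) and Rragd (5.71) rose. Elovl3 (-6.83, SE 1.02), the epidermal keratin gene Krt1 (-5.21, SE 0.24), Fhdc1 (-5.12), Slco1a1 (-4.89) and Sult2a8 (-4.67) fell. Ctrl, a pancreatic protease gene, was listed at or near 0 on all mutant arrays of 3 months, so its size has no lower reference, and it lost its call on the log2(signal + 16) scale (adjusted p = 0.110). Its call ended in 3 of 18 fits without 1 array and that of Slco1a1 in 1, and Sult2a8 changed by -3.04 without mutant replicate 1 of 15 months.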

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

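The tests of the array-wide shift, of batch, of cell share and of biliary markers were chosen after the results they test were seen, and so were the genes of the muscle and enterocyte lists.

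A sample far from the others of its group was found in 36 of 558 groups of 5 arrays, while chance marks about 1 in 20 (27.9). Groups of 3 were not tested. Replicate 5 of wild type at 3 months stood apart for the array median (6.47 against a mean of 6.36). Replicate 4 of wild type at 3 months stood apart for Abhd5 (7.56 against a mean of 7.90), Cbr3 (6.16 against a mean of 5.09), Ccng1 (8.22 against a mean of 8.85) and Fabp4 (4.29 against a mean of 6.86). Replicate 1 of wild type at 3 months stood apart for Acaa1b (9.98 against a mean of 11.88), Cp (13.04 against a mean of 12.35), Fabp1 (11.35 against a mean of 12.87), Me1 (9.75 against a mean of 10.64), Moxd1 (13.13 against a mean of 2.86), S100a11 (8.54 against a mean of 7.84), Slco1a1 (6.03 against a mean of 9.67) and Timp2 (7.27 against a mean of 6.53). Replicate 3 of wild type at 3 months stood apart for Apbb1 (9.28 against a mean of 9.61), Cyp2u1 (8.02 against a mean of 9.21) and Myoz1 (8.28 against a mean of 3.98). Replicate 3 of mutant at 3 months stood apart for Ctrl (0.014 against a mean near 0). Replicate 5 of mutant at 3 months stood apart for Cxcl16 (6.81 against a mean of 7.53) and Ehf (7.03 against a mean of 7.49). Replicate 4 of mutant at 3 months stood apart for Cybb (7.66 against a mean of 8.14), Elovl3 (11.46 against a mean of 9.70), Rheb (7.96 against a mean of 8.31) and Zfp760 (4.05 against a mean of 5.59). Replicate 2 of mutant at 3 months stood apart for Ifi27l2a (7.16 against a mean of 5.75), Itgb6 (3.74 against a mean of 4.82) and Pparg (8.97 against a mean of 8.37). Replicate 4 of wild type at 15 months stood apart for the acinar mean (6.07 against a mean of 5.51), Acmsd (6.85 against a mean of 7.65), Enho (7.49 against a mean of 8.92), Gsk3b (8.90 against a mean of 9.21) and Pparg (8.86 against a mean of 7.93). Replicate 3 of wild type at 15 months stood apart for D17H6S56E-5 (8.76 against a mean of 6.90), Jun (7.78 against a mean of 6.82) and S100a11 (9.61 against a mean of 8.14). Replicate 5 of wild type at 15 months stood apart for Kif11 (4.01 against a mean of 4.77). Replicate 1 of wild type at 15 months stood apart for Nudt7 (11.80 against a mean of 10.18).

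The mutant effect differed between 15 and 3 months, by a test of the difference itself, for 86 of the named genes. The named genes were chosen on these same arrays, many by the size of their change and some by this test. Their number is therefore no result beyond the 1934 of all 19933 genes (9.70%) that passed. It was more positive at 15 months for Apbb1 (2.60), Btg2 (1.54), Cbr3 (3.40), Ccl2 (2.94), Ccl20 (6.41), Ccna2 (1.98), Ccnb2 (3.40), Cd24a (3.81), Cd34 (2.23), Cd9 (1.495), Cdh1 (4.62), Cdh17 (5.53), Cdk1 (2.02), Cldn7 (4.42), Col12a1 (2.80), Cx3cl1 (2.35), Cxcl16 (1.56), D17H6S56E-5 (4.04), Dusp1 (1.63), Ehf (5.44), Elovl7 (4.82), Ezr (2.74), Fn1 (1.58), Golm1 (2.57), Gp2 (7.23), Guca2b (7.07), Hhatl (1.69), Hk2 (3.08), Ier3 (2.57), Ifit2 (1.75), Itgam (3.11), Itgax (2.02), Lepr (2.27), Mki67 (2.69), Mmp8 (1.52), Nipal1 (1.74), Pfkp (1.65), Phlda3 (2.81), Pkm (1.55), Pnpla3 (2.98), Prom1 (4.21), Psat1 (4.67), Reg3g (6.16), S100a8 (2.59), Scn8a (4.53), Sesn2 (1.46), Slc2a1 (2.14), Slc7a11 (4.63), Tgfb2 (4.99), Timp1 (2.64), Timp2 (1.74), Timp4 (5.41), Top2a (2.80), Trpv4 (3.75) and Vwf (2.23). It was more negative for Cat (-1.18), Cidea (-4.56), Clec4g (-2.40), Cox6c (-0.96), Cox7a2 (-1.04), Cyp2a22 (-3.18), Cyp2j5 (-1.11), Cyp2u1 (-1.75), Cyp8b1 (-3.38), Elovl3 (-5.82), Fabp1 (-2.81), Fbp1 (-0.87), Fitm1 (-2.08), G6pc (-1.81), Hgd (-0.95), Hsd3b7 (-1.62), Me1 (-1.50), Mup21 (-4.17), Mup3 (-4.37), Nudt7 (-2.48), Saa4 (-2.69), Serpina7 (-3.56), Slc27a2 (-0.96), Slco1b2 (-2.41), Sult2a8 (-5.63), Sult5a1 (-2.97), Themis (-4.04), Uox (-1.68), Vmn2r76 (-4.47), Zfp760 (-3.36) and Zmat1 (-4.65). Of all genes, 63 passed this test with the Y-linked mean as a covariate, against 1934 without it.

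Among the gene lists, the shift differed between the ages in the same test. It was more positive at 15 months for cell cycle and proliferation (1.07), cholangiocyte and progenitor markers (3.46), macrophage and Kupffer cell markers (0.52), neutrophil markers (0.80), oncofetal and liver tumour markers (2.11), pancreatic acinar markers (2.71) and stellate cell and extracellular matrix (1.46). It was more negative for bile acid synthesis and transport (-0.71), drug-metabolising cytochrome P450s (-0.83), fatty acid oxidation and PPARa targets (-0.55), hepatocyte identity (-0.21), male-biased liver genes (-0.94), NRF2 and glutathione metabolism (-0.44), oxidative phosphorylation (-0.49) and pericentral and Wnt target genes (-0.79). With an estimated correlation 0 of these 15 lists passed (lowest adjusted p = 0.0790). Without mutant replicate 1 of 15 months the value was -0.11 for pericentral genes (adjusted p = 0.258), -0.12 for hepatocyte identity (adjusted p = 0.0638), -0.35 for male-biased genes and -0.39 for P450s. Without mutant replicate 2 of 15 months it was 0.23 for macrophage markers (adjusted p = 0.0717) and 0.64 for cell cycle genes. Without mutant replicate 3 of 15 months it was 0.80 for macrophage markers, -1.40 for P450s and -0.54 for hepatocyte identity, which was -0.36 and -0.39 without wild type replicates 3 and 4 of that age. The macrophage call also ended without wild type replicate 1 of 3 months (adjusted p = 0.0892), and the NRF2 call ended in 6 of 18 fits without 1 array (highest adjusted p = 0.0825). The macrophage value was -0.0729 (adjusted p = 0.616) with the Y-linked mean as a covariate, which also ended the calls of the fatty acid oxidation, hepatocyte identity, neutrophil and acinar lists. The acinar value was 1.31 without wild type replicate 5 of 3 months (adjusted p = 0.0745) and -0.0976 without arrays with high acinar or muscle signal.

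Probe sets with no single gene name, outside the comparisons of the report, numbered 7082. Of these, 105 passed the test at 3 months (96 higher and 9 lower in mutant livers) and 196 at 15 months (106 higher and 90 lower).

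Acinar genes were lower in mutant livers at 3 months. Pancreatic tissue carried over with some livers needs these genes to move together between arrays, and their median pairwise correlation, after removal of group means, was 0.8506. If the genotype lowers acinar genes in liver, wild type arrays should lie above the mutants. The number of wild type arrays inside the mutant range was 0, but 1 of 5 lay below all mutants, and the reading of this test was made stricter after that was seen, so the genotype cannot be told apart from sampling here (exact permutation p = 0.0476). Carry-over in wild type replicates 1 and 5 is therefore a likely source, as a hypothesis.

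Many genes differed between 15 and 3 months in each genotype (7582 in wild type and 4791 in mutant livers). An array-wide intensity shift as the whole source is argued against, since 71.34% of the wild type calls were still called, in the same direction, after quantile normalization. The balance of the wild type calls did change, from 5418 higher and 2164 lower to 3247 higher and 3290 lower. The labels name no batch, but the serial numbers of the samples fell in separate ranges for the ages. A processing batch that goes with age, if there was one, cannot be told apart from age. The age effects in wild type and mutant had a Pearson correlation of 0.48 across genes, which either of them would allow. Genes of other tissues were also higher on every array of 15 months than on the mutant arrays of 3 months. Acinar means were 5.35 to 6.07 against 2.63 to 2.82, and muscle means 5.63 to 6.12 against 3.90 to 4.03. The cause of this rise was not tested.

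Cholangiocyte, stellate cell, macrophage and neutrophil markers were shifted upward in mutant livers at 15 months, while endothelial (6 of 22 higher, 2 lower, camera adjusted p = 0.295) and T, B and NK cell markers (0 of 28 called) were not. With an estimated correlation the macrophage and neutrophil lists did not pass (adjusted p = 0.330 and adjusted p = 0.198). A lower hepatocyte share alone would raise all other cell types alike only if their markers lay above the floor and were not expressed in hepatocytes. The highest and lowest list medians differed by 3.844 (cholangiocyte against T, B and NK cell markers). Marker levels were not matched between the lists, so this difference cannot rule out a lower hepatocyte share. The 18 enterocyte genes, chosen after the results were seen, had a median of -0.08849, with 2 of them higher. For these genes the median argues against intestinal tissue carried over with the mutant livers, but a list so chosen is not independent support. Biliary cells cannot be told apart from hepatocytes that express biliary genes in whole tissue, where 20 of 22 cholangiocyte markers rose. Both stay open, as does a biological difference of the tumour stage.

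Other splits of the same arrays into groups of the same sizes gave as many genes as the real split, itself included, in 1 of 100 splits (real value 876, highest other 8) at 3 months and in 1 of 56 splits (real value 2255, highest other 362) at 15 months. For age the counts were 1 of 100 splits (real value 7582, highest other 1107) in wild type and 1 of 56 splits (real value 4791, highest other 2) in mutant livers. They were 1 of 100 splits (real value 1934, highest other 821) for the difference between the ages and 1 of 100 splits (real value 122, highest other 0) for genes changed alike at both ages. No other split reached the real value for these 6 counts of genes. Chance alone is thus an unlikely source of the counts other than that of genes changed alike. Chance is not excluded, since 1 of 56 or 1 of 100 is the lowest share these tests can give. Splits that call few genes at 3 months can share few between the ages, so a shared count near 0 was set beforehand. That test therefore cannot decide whether 122 is more than lists of these sizes would share. The numbers of gene lists could arise by chance. As many were called in 27 of 100 splits (real value 8, highest other 13) at 3 months. The counts were 12 of 56 splits (real value 18, highest other 21) at 15 months and 24 of 100 splits (real value 15, highest other 21) for the difference.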

How the results depend on the processing

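The log2(signal + 16) scale and the fits without arrays with most zeros, high acinar or high muscle signal were chosen after seeing the data, and the Y-linked mean as a covariate was run after seeing the results. The counts reported were 876 for 3 months, 2255 for 15 months, 1934 for the difference between the ages, 7582 for age in wild type, 4791 for age in mutant, 122 for genes changed alike at both ages, 8 for lists at 3 months, 18 for lists at 15 months and 15 for lists of the difference. Those that changed by more than 1.5 times are given here. Without the dimmest 25% of genes the counts were 1430 for 3 months and 186 for genes changed alike at both ages. Without the dimmest 50% of genes the counts were 1500 for 3 months, 5013 for age in wild type and 4 for lists at 3 months. With trend and robust eBayes the counts were 1429 for 3 months and 195 for genes changed alike at both ages. With array weights the counts were 1385 for 3 months. With only the groups compared in the fit the counts were 357 for 3 months, 1471 for 15 months and 53 for genes changed alike at both ages. On the log2(signal + 16) scale the counts were 192 for genes changed alike at both ages. With the Y-linked mean as a covariate the counts were 189 for 3 months, 1127 for 15 months, 63 for the difference between the ages, 2528 for age in wild type, 13 for lists at 3 months and 39 for genes changed alike at both ages. Without the 2 wild type arrays with most zeros the counts were 147 for 3 months, 1203 for the difference between the ages, 14 for lists at 3 months and 63 for genes changed alike at both ages. Without arrays with high acinar signal the counts were 349 for 3 months. Without arrays with high acinar or muscle signal the counts were 120 for 3 months, 835 for the difference between the ages, 4811 for age in wild type, 5 for lists at 3 months and 43 for genes changed alike at both ages. In camera with an estimated correlation the counts were 0 for lists at 3 months, 3 for lists at 15 months and 0 for lists of the difference. In fry the counts were 3 for lists at 3 months and 9 for lists of the difference. Leaving out each array in turn gave 253 to 1255 for 3 months, 1269 to 2476 for 15 months, 1139 to 2244 for the difference between the ages, 6686 to 7668 for age in wild type, 3405 to 5110 for age in mutant, 53 to 163 for genes changed alike at both ages, 6 to 12 for lists at 3 months, 18 to 21 for lists at 15 months and 13 to 16 for lists of the difference. Fewer genes or arrays enter some of these fits; otherwise the cause was not tested.

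With the replicate number as a block the counts were 1066 for 3 months, 1824 for 15 months, 1750 for the difference between the ages, 7571 for age in wild type, 4286 for age in mutant, 8 for lists at 3 months, 18 for lists at 15 months, 15 for lists of the difference and 121 for genes changed alike at both ages. The numbers did not pair the samples: residual correlations between arrays of the same number had a median of 0.0149 (-0.196 to 0.149), against -0.184 to 0.198 for different numbers.

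Of 41 called gene lists, 32 kept their call whichever array was left out, and of 203 called gene results 139 did. The sign changed for results that had not passed. Without arrays with high acinar signal Gpc3 at 3 months was 0.2010 and Alb -0.0029. Without arrays with high acinar or muscle signal Gpc3 was 0.2972, Alb -0.0245 and Xist 0.5150. With each array left out in turn, Gpc3 ranged from -0.3196 to 0.1998, Alb from -0.0173 to 0.0909 and Xist from -0.9637 to 0.1003. The acinar list, called for the difference between the ages, changed sign to -0.0976 without arrays with high acinar or muscle signal. The macrophage list, also called for that difference, changed sign to -0.0729 with the Y-linked mean as a covariate (adjusted p = 0.616). Under that covariate 68 of 214 gene results and 7 of 41 gene lists were weaker. Without arrays with high acinar or muscle signal 50 of 214 gene results and 4 of 41 lists were weaker. Without arrays with high acinar signal 33 gene results and 5 lists were weaker. The cause was not tested. The check of Pten and the pseudocount for linear values were not run. Signal near the floor limits changes of dim genes.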

Other observations

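The lists were also tested in the age comparisons, a choice made after seeing the data. In wild type livers the cell cycle list (median -0.72, 18 of 38 lower and 4 higher) and the cholangiocyte list (median -0.20, 9 of 22 lower and 2 higher) were shifted downward and interferon-stimulated genes (median 1.11, 18 of 26 higher) upward from 3 to 15 months. Their camera adjusted p-values were 9.5e-07, 0.0125 and 0.00103, and with an estimated correlation each had an adjusted p = 0.970. In mutant livers the cell cycle list was not shifted (median 0.01, camera adjusted p = 0.502). The cholangiocyte list (median 1.93, 14 of 22 higher, camera adjusted p = 4.75e-07) and interferon-stimulated genes (0.52, adjusted p = 0.0184) were shifted upward. So were the stellate (1.38, adjusted p = 2.22e-05), macrophage (1.44, adjusted p = 9.68e-05), oncofetal (1.53, adjusted p = 0.00969) and chemokine lists (0.92, adjusted p = 0.00416). Fatty acid oxidation (-0.70, adjusted p = 2.12e-07), male-biased (-0.95, adjusted p = 5.58e-06), oxidative phosphorylation (-0.26, adjusted p = 6.02e-05) and bile acid genes (-0.68, adjusted p = 7.78e-05) were shifted downward. So were pericentral genes (-0.51, adjusted p = 0.000415), hepatocyte identity (-0.18, adjusted p = 0.00474) and P450s (-0.21, adjusted p = 0.0187). With an estimated correlation none of these 13 lists passed (lowest adjusted p = 0.230). A difference in processing between the ages, which the labels do not name, was not tested in these values.

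Of 20 skeletal muscle genes, chosen after seeing the data, none rose and 1 fell in mutant livers at 3 months (median -1.46). Of 18 enterocyte genes, chosen in the same way, 2 rose and none fell at 15 months (median -0.09).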
